A study of Mus musculus with 2 samples.

How the data were processed

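Small RNA of under 30 nt was sequenced from total RNA of 2 pools of kidneys at 15.5 days, per the labels. The deposited files give, for each library, raw read counts per miRNA gene without regard to strand, on the gene's own strand and on the opposite strand. Per the notes deposited with the files, the authors made these counts from alignments to the mm10 assembly with the GENCODE M4 annotation. The aligner, the counting program and their versions are not given in the sources used here. Reads outside genes have lines of their own in the files and were kept out of library sizes. In replicate 1 and replicate 2 they were unmapped reads (17.7% and 19.7% of reads), reads matching several loci (27.1% and 26.6%) and reads in no annotated gene (2.57% and 4.05%), with 0 ambiguous reads. Since reads matching several loci were set apart, a miRNA gene with near-identical copies can have a low count whatever its level. Signal tracks named in the deposited notes were not used here.

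Own-strand counts were used throughout, because they held all but 2.16% and 2.33% of the gene reads. Counts were divided by the library's sum over miRNA genes and given as CPM (counts scaled to a library total of 1000000) or percent. With 7434182 and 5863293 such reads, a count of 0 allows up to 3 counts, or 0.404 and 0.512 CPM. Gene names, positions and hairpin sequences came from GENCODE M21 on the same assembly, matched by gene identifier, which gave a name to 1894 of 1973 genes. The 79 unmatched genes held 5 reads in all. Of the matched genes, 919 share a stretch of 20 nt with a miRNA gene elsewhere, and they are named as sharing sequence. M21 lists 308 miRNA genes that have no line in the files and were not analysed here.

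The gene lists, the rule for named genes, the tests of the main results and most alternatives were fixed before the data were examined. Tests of an origin or explanation were chosen after the results were seen. The named genes are the 25 with the highest mean CPM, the 3 highest members of each list (2 for a list of fewer than 5 measured members), and, among genes with a mean count of at least 100, the 5 with the highest and the 5 with the lowest ratio between libraries. The genes given with a count of 0, those named for opposite-strand reads, the lowest members of clusters, Mir133b and Mir541 fall outside this rule and were chosen after their values were seen. Clusters join genes on 1 strand that lie within 10 kb of each other. The mean and SD are over 2 libraries, and intervals are 95% exact (Clopper-Pearson) binomial intervals. With 1 group there was no contrast to fit. edgeR 4.0.16 gave the common dispersion of a model with an intercept alone and the TMM factors, and DESeq2 1.42.0 gave size factors, both in R 4.3.3. The other steps used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

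Counts of the libraries were compared with a two-sided exact binomial test given the library totals, for genes with a mean count of at least 10, with Benjamini-Hochberg adjustment at 0.05 and a fold of at least 2. This test covers counting error and compares libraries only. The shift of a list was its median log2 ratio of CPM, set among 10000 random lists drawn from the 50 genes nearest in mean expression to each member, the list's own members included. It was computed for the 19 lists with at least 3 members of a mean count of 10. Alternatives tried were other scalings, count filters, pseudocounts, fold thresholds, both strands summed, gene copies summed, the most abundant gene left out, each replicate left out, and genes sharing sequence left out. The last was added after the data were seen.

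The dispersion and the binomial test were tried on simulated libraries drawn from the measured means, for replicate 2 against replicate 1. Dispersions of 0, 0.1 and 0.3 (as coefficients of variation) came back as 0.0100, 0.106 and 0.312 over 729 genes. The binomial test was tried on 2 designs. With 200 genes changed, up and down in turn and outside the 25 most abundant, it called 91.8% of genes changed 2.5-fold, 100% of those changed 4-fold and 0 unchanged genes, over 376 genes. With 200 genes all raised and abundant genes among them, it called 0% of genes raised 2.5-fold, 21% of those raised 4-fold and 126 unchanged genes, over 370 genes, because the changes moved the library totals. The first version of this step used the one-sided design, and the balanced design was added after that result. The calls between the libraries thus hold only where changes are few or balanced. With no gene changed it called 0 of 379 genes. The list shift was tried on independent normal values in place of counts, with lists of 15 genes picked at random. With no shift, 5 of 100 lists lay outside the central 95%, and 100 of 100 lists shifted by 0.6 on the log2 scale lay above it. Smaller shifts, and lists whose members vary together, were not tried.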

Results

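MicroRNA sequencing was carried out on kidneys of mouse embryos of the B6NCrl strain at 15.5 days of development, when the organ holds growing ureteric epithelium, nephron progenitors, forming nephrons, stroma and vessels. The samples form 1 group of 2 libraries, labelled as biological replicates, and each library is a pool of kidneys from embryos of both sexes. The pools came from 78 embryos (replicate 1) and 62 embryos (replicate 2). The files hold 14419931 and 12102315 reads, of which 7434182 and 5863293 lay on the gene's own strand within a microRNA (miRNA) gene. Each value is for the whole hairpin gene, so the arms of a hairpin are not told apart. The design holds no second tissue, age or treatment, so the data answer which miRNA genes the E15.5 kidney carries and how closely the pools match. No comparison of groups was made.

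A few miRNA genes supplied most of the counts. Mir10a, which lies in the Hoxb cluster, was the most abundant at 15.4% ± 1.87 of counts (SD, n = 2). Mir335, in an intron of the imprinted gene Mest, followed at 6.68% ± 0.191, and Mir10b, in an intron annotated to Hoxd3 and Hoxd4, at 6.16% ± 0.529. The let-7 genes Mirlet7g and Mirlet7i stood at 5.30% ± 0.00618 and 5.29% ± 0.701, and Mir126a, encoded within the endothelial gene Egfl7, at 4.88% ± 0.135 (SD, n = 2 each). Mir322 reached 4.01% ± 0.133 and Mir99a 3.79% ± 0.0435. These 8 genes held 50% of the counts, 50 genes held 90% and 142 genes held 99%. The 25 most abundant genes together took 79.4% ± 1.21, and 23 genes were among the top 25 of both libraries. These shares leave out reads that match several loci, of which there were 0.525 (replicate 1) and 0.550 (replicate 2) per own-strand gene read. Genes with near-identical copies can thus stand too low. The ranking covers own-strand counts of genes in the files. Mir378a has no line there, and the reads opposite to Gm25301, which overlaps it on the other strand, had a mean of 64485.5, above the mean of 47212 reads of Mir100 at rank 25. Of 1973 miRNA genes in the files, 394 reached 1 CPM (counts scaled to a library total of 1000000) in both libraries, 173 reached 100 CPM and 81 reached 1000 CPM. No own-strand read fell in 1244 genes, and a count of 0 allows up to 0.404 CPM in replicate 1 and 0.512 CPM in replicate 2. Intervals and such floors cover counting error only.

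**Figure D1:**
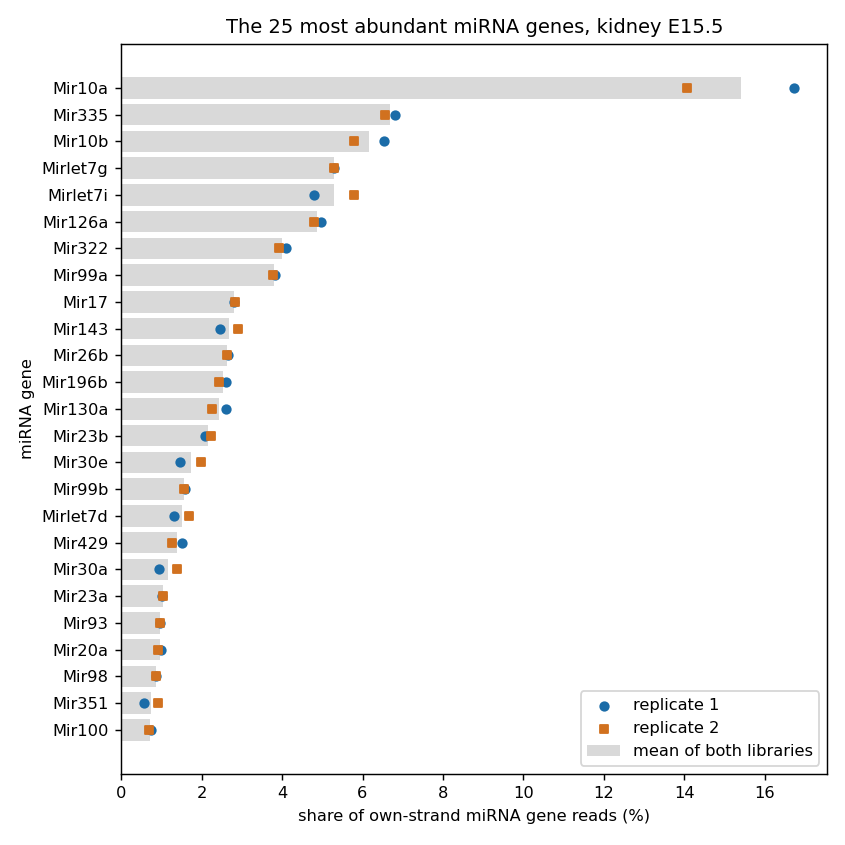
Share of own-strand miRNA gene reads (%) of the 25 miRNA genes in the files with the highest mean CPM in kidney at E15.5. Bars give the mean of both libraries, circles replicate 1 and squares replicate 2, and Mir10a stands apart from the rest at a mean of 15.4%.

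The most abundant genes are placed as follows in the mm10 (GRCm38) assembly, with names and positions from GENCODE M21. Mir10a (ENSMUSG00000065519.1) lies on chromosome 11 from 96317165 to 96317274, outside any other gene annotated on its strand. Mir335 (ENSMUSG00000065501.1) is intronic to Mest on chromosome 6, from 30741299 to 30741396. Mir10b (ENSMUSG00000065500.2) lies on chromosome 2 from 74726070 to 74726137. Mirlet7g (ENSMUSG00000065440.1) is in an intron of Wdr82 on chromosome 9, from 106178840 to 106178927. Mir126a (ENSMUSG00000065540.1) overlaps an exon annotated to Egfl7 or Gm20532 on chromosome 2, from 26591357 to 26591429. Of the 394 genes detected in both libraries, 170 were intronic, 108 overlapped an exon and 116 were intergenic.

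The 5 miRNA genes of the Hox clusters, which share the positional expression of their Hox neighbours, formed the largest of the 21 lists fixed in advance, with 24.4% ± 2.46 of counts (SD, n = 2). Mir10a exceeded Mir10b by 2.56 times in replicate 1 and 2.43 times in replicate 2, and Mir196b, which overlaps an exon of Hoxa9, reached 2.52% ± 0.122. The let-7 family, known for its part in developmental timing, held 13.6% ± 1.03 over 10 measured members. Mirlet7d followed Mirlet7g and Mirlet7i at 15045 ± 2648 CPM, and Mir98, in an intron of Huwe1, reached 0.859% ± 0.00942. Mirlet7e and Mirlet7f-1 were not analysed here, and 5 of the 10 measured members share sequence with another miRNA gene. The let-7 share can therefore be too low. In the Hox list 2 of 5 members share sequence, but Mir10a, Mir10b and Mir196b do not. The order of the lists thus holds for these counts only. The miR-99/100 and miR-125 families took 6.44% ± 0.0214, led by Mir99a, Mir99b at 1.57% ± 0.0211 and Mir100 at 0.707% ± 0.0344. Of their 6 members 2 share sequence with another miRNA gene, so this order can come from reads set apart. With Mir10a taken out of both the Hox list and the total, the rest of the list held 10.6%, below the let-7 family.

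The miR-17-92 cluster, which promotes proliferation of progenitor cells and is needed in nephron progenitors, held 6.21% ± 0.0671 of counts together with its paralogs. All 15 members of this list reached 1 CPM in both libraries. Mir17 stood at 2.81% ± 0.00620, Mir93, within Mcm7, at 0.963% ± 0.0111 and Mir20a at 0.957% ± 0.0568 (SD, n = 2 each). The members of the cluster on chromosome 14, between 115043671 and 115044506, summed to 4.46% ± 0.00644. A cluster of 7 genes on the X chromosome, between 53047997 and 53054349, summed to 4.93% ± 0.114. It is led by Mir322, with Mir351 next at 0.734% ± 0.241. In all, 104 clusters of neighbouring genes held 38.8% of counts.

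Lists tied to the compartments of the developing kidney were all present. The miR-30 family, known from nephron epithelium and podocytes, held 3.31% ± 0.785, with Mir30e at 1.72% ± 0.375, Mir30a at 1.16% ± 0.314 and Mir30d at 0.397% ± 0.0957 (SD, n = 2 each). The epithelial miR-200 family held 2.31% ± 0.248. Its leading member was Mir429 at 1.39% ± 0.161, above Mir200c at 0.402% ± 0.0106 and Mir200b at 0.393% ± 0.0828. Genes of stroma and mesenchyme held 3.40% ± 0.309, and most of it was Mir143, a smooth muscle miRNA, at 2.68% ± 0.311. Of the 9 members, 5 share sequence with another miRNA gene, so their counts can be too low. Mir214 stood at 0.413% ± 0.0523 and Mir140, known from cartilage, at 0.214% ± 0.0536. The endothelial list held 4.91% ± 0.130, nearly all from Mir126a, with Mir221 at 238 ± 21.4 CPM.

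The list of miRNAs known as enriched in adult kidney was low at this age, at 0.0441% ± 0.0106 of counts (SD, n = 2). Mir204 stood at 200.4 ± 47.3 CPM, Mir192 at 155 ± 51.8 CPM and Mir194-2 at 73.4 ± 6.88 CPM. Mir194-2 shares sequence with another miRNA gene, and reads that match several loci are in no gene's count. No adult kidney was analysed here, so no change with age was measured.

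Genes of imprinted domains varied in level. The Dlk1-Dio3 domain on chromosome 12 held 2.74% ± 0.513 over 44 measured members, 40 of which reached 1 CPM in both libraries. Another 6 members were not analysed here, so this share can be too low. Among them are Mir409, Mir376a, Mir299a and Mir380. Reads opposite to the genes that overlap them had means of 16829.5, 6767.5, 4792 and 2272. Mir411 led at 4740.5 ± 1221 CPM, with Mir487b at 3712 ± 53.7 CPM and Mir127 at 3239.8 ± 885 CPM (SD, n = 2 each). Mir411 and Mir487b share sequence with another miRNA gene, and Mir127 does not. Mir483, in an intron of Igf2, exceeded Mir675, within H19, at 1089.5 ± 218 CPM against 70.4 ± 1.85 CPM. The miR-181 family held 0.938% ± 0.0405, led by Mir181c at 4001 ± 705 CPM, Mir181d at 2973 ± 594 CPM and Mir181a-1 at 1444 ± 548 CPM. Of its 6 members 4, Mir181a-1 among them, share sequence with another miRNA gene. Their counts can be too low, so this order can come from reads set apart. The repeated families of the Sfmbt2 intron held 0.527% ± 0.0186, led by Mir467d at 1571 ± 133 CPM, Mir467e at 1429 ± 77.8 CPM and Mir467c at 1329 ± 151 CPM. Since 67 of the 69 members of those families share sequence with another miRNA gene, their counts are uncertain. Mir34c stood at 495 ± 60.6 CPM, Mir34a at 101 ± 4.32 CPM and Mir449a at 42.4 ± 5.15 CPM, and the list of both families held 0.0657% ± 0.00484. The pluripotency clusters were lowest of all lists at 0.00425% ± 0.00140, with Mir302d at 12.6 ± 3.17 CPM, Mir302a at 12.2 ± 3.74 CPM and Mir302b at 5.65 ± 1.90 CPM. Mir302a and Mir302b share sequence with other miRNA genes, and the list held 0.00253% without such genes.

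Markers of other tissues and of blood held small shares, but by mean most of these lists stood above the kidney-enriched list at 0.0441%. By mean only the erythroid list was below it, and this order changed between the libraries. In replicate 1 the kidney-enriched list (0.0516%) was above the erythroid list (0.0352%) and Mir122 (0.0319%). In replicate 2 the kidney-enriched list (0.0366%) was below both, at 0.0488% and 0.0628%. The endocrine list held 0.166% ± 0.0446, mostly Mir375 at 1460.1 ± 307 CPM, with Mir7b at 119 ± 112 CPM and Mir7-1 at 73.7 ± 21.98 CPM. The muscle list held 0.0865% ± 0.0230, mostly Mir206 at 809 ± 212 CPM, with Mir208b at 24.5 ± 9.09 CPM and Mir499 at 19.97 ± 2.19 CPM. The neural list held 0.0720% ± 0.0104, with Mir132 at 396 ± 32.2 CPM, Mir137 at 172 ± 64.7 CPM and Mir128-1 at 73.9 ± 12.9 CPM. The leukocyte list held 0.0660% ± 0.00571, with Mir223 at 393 ± 0.364 CPM, Mir155 at 255 ± 54.9 CPM and Mir150 at 11.5 ± 1.82 CPM. Mir142 was not analysed here, and 3459 and 2995 reads opposite to Mir142b, which overlaps it on the other strand, more than the 2920 and 2306 reads of Mir223, raised the list to 0.112% when both strands were counted. Mir122, the hepatocyte miRNA, stood at 474 ± 219 CPM. The erythroid list held 0.0420% ± 0.00965, with Mir451a at 313 ± 82.6 CPM and Mir144 at 89.96 ± 7.37 CPM (SD, n = 2 each). Its members Mir451b and Mir486b were not analysed here. In the muscle list 4 of 9 measured members, and in the neural list 9 of 12, share sequence with another gene, among them Mir1a-1, Mir133a-1 and the Mir124 genes, which stood at 0. Their counts of 0 do not show that these miRNAs were absent.

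**Figure D2:**
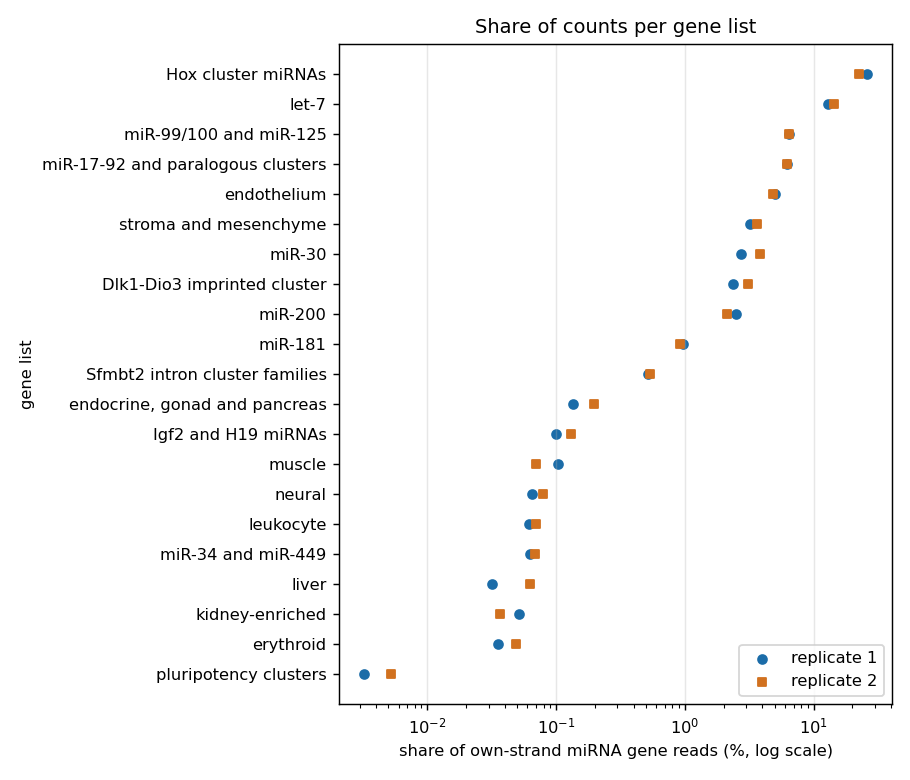
Share of own-strand miRNA gene reads (%, log axis) of the 21 gene lists in kidney at E15.5. Circles are replicate 1 and squares replicate 2, and the lists run from the Hox cluster miRNAs (mean 24.4%) down to the pluripotency clusters (mean 0.00425%).

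The pools were close in rank and level, but differed by far more than counting error. Among the genes with a mean count of at least 100, 96.6% lay within 2-fold, and the median absolute log2 ratio was 0.25 over 264 genes. Of these genes, Mir6236 had the largest ratio of replicate 2 over replicate 1, at a log2 of 3.34 (95% exact binomial interval 3.06 to 3.63), from 114 and 909 reads. Mir7b followed at 2.31 (2.12 to 2.497), Gm23935 at 2.26 (2.05 to 2.47), Mir138-1 at 1.31 (1.04 to 1.57) and Mir770, within Meg3, at 1.10 (0.85 to 1.36). Among the same 264 genes, the lowest were Mir181a-1 at -0.79 (-0.84 to -0.75), Mir208b at -0.78 (-1.12 to -0.44), Mir192 at -0.69 (-0.83 to -0.56), Mir33 at -0.54 (-0.79 to -0.30) and Mir206 at -0.54 (-0.60 to -0.49). Gm23935, Mir138-1 and Mir181a-1 share sequence with another miRNA gene.

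Across 729 genes, Pearson's r of log2(CPM + 1) was 0.993 and Spearman's rho 0.923. Genes are not independent replicates, so no p-value is given. The biological coefficient of variation was 0.255. A chi-square of 198 per degree of freedom, over 456 degrees of freedom, set the libraries apart from a single library deposited again. By a two-sided exact binomial test with Benjamini-Hochberg adjustment at 0.05, which compares these libraries and not conditions, 211 of 378 genes differed, 152 higher and 59 lower in replicate 2, and 23 of them by at least 2-fold. The 211 are neither few nor balanced in direction, and in a simulation with all changes upward the test called 126 unchanged genes, so these counts depend on the library totals. Of the 23, 22 were higher in replicate 2 and 1 was lower. The lower one was Mir133b, with 91 and 14 reads and a log2 ratio of -2.36 (-3.29 to -1.54), which shares sequence with another miRNA gene and was named after its value was seen. This split rests on the scaling, since 15 were higher and 7 lower with TMM, and 14 higher and 8 lower with DESeq2 size factors. Those scalings moved every log2 ratio by -0.13 and -0.16.

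**Figure D3:**
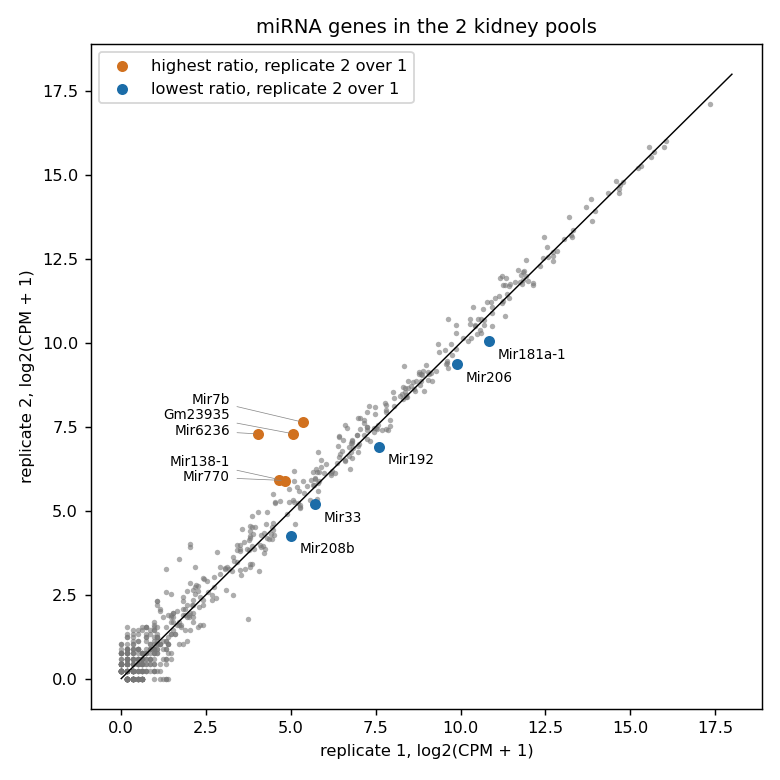
Level of each miRNA gene with a read in either library, as log2(CPM + 1), replicate 1 on the horizontal and replicate 2 on the vertical axis. Points are genes, the line marks equal levels, and the 5 genes with the highest and the 5 with the lowest ratio among those with a mean count of at least 100 are named, with Mir6236 at the highest log2 ratio of these, 3.34.

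Some gene lists moved together between the pools. The median gene of the Dlk1-Dio3 domain had a log2 ratio of 0.36, above 99.75% of random lists of matched expression, and 32 of its 40 members with enough counts lay above the median of all genes. Some markers of other tissues were also higher in replicate 2. Mir122 had a log2 ratio of 0.98, the erythroid list a median of 0.54 with 3 of 3 members higher, and the endocrine list a median of 0.62 with 4 of 5 higher. The erythroid and endocrine medians lay at the percentiles 90.3 and 95.3 of random lists. The neural and leukocyte medians, 0.12 and 0.32, lay lower, at the percentiles 38.6 and 76.6. The let-7 and pluripotency medians, 0.33 and 0.67, reached higher percentiles, 96.2 and 96.3, so a high value was not particular to markers of other tissues. The miR-200 family had a median of -0.24, above only 0.69% of random lists, and 0 of its 5 members lay above the median of all genes. The muscle list had a median of -0.38, above 0.80% of random lists, with 1 of 6 members above that median. Without the genes that share sequence, the muscle list stood at -0.22 and at the percentile 6.88, inside the central 95%. The other 16 of 19 lists lay within the central 95% of random lists, and chance would put 0.95 of the 19 lists outside it. The value of 0.95 holds for members that vary independently. Members of a cluster can be made from shared transcripts, so chance can put more lists outside than that. The percentiles describe these libraries and are not p-values.

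**Figure D4:**
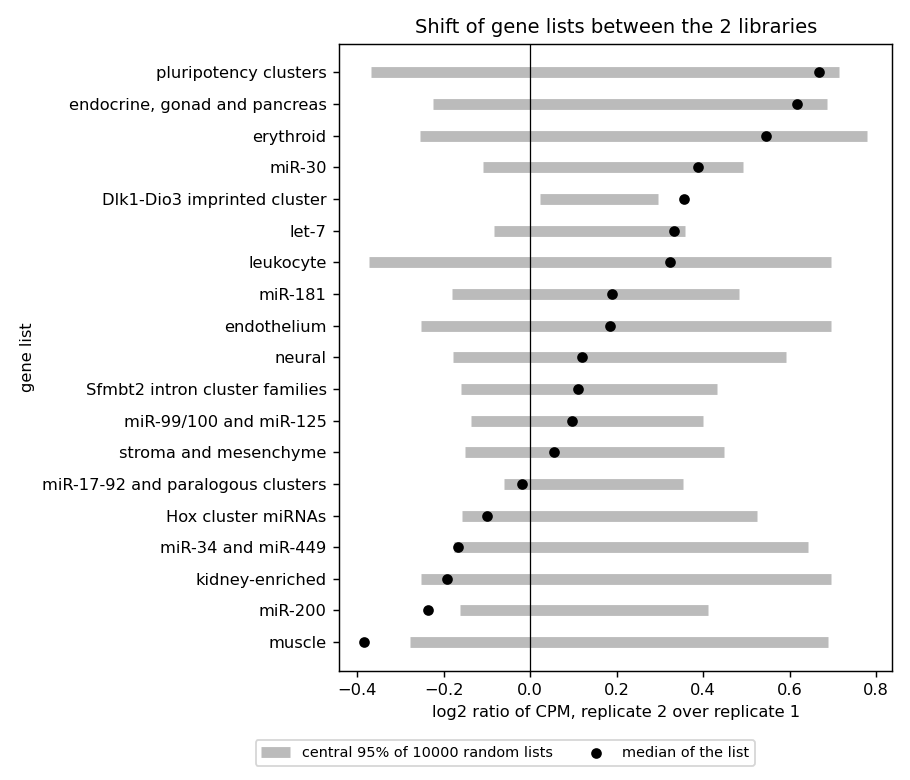
Median log2 ratio of CPM, replicate 2 over replicate 1, of 19 gene lists (points), with the central 95% of 10000 random lists matched on expression (grey bars). The Dlk1-Dio3 list lies above its bar at 0.36, and the miR-200 and muscle lists lie below theirs at -0.24 and -0.38.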

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

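All tests in this part were chosen after the result was seen. The values given here are signals in data that the report's comparisons did not use, above what a count of 0 allows, and no control sample exists.

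Reads on the strand opposite to a miRNA gene were concentrated on 9 genes, which held 99.0% of such reads in either library. Gm25301 had 75709 opposite-strand reads in replicate 1 and 53262 in replicate 2, against 0 on its own strand. Gm25927 had 33064 and 34535, Gm24321 had 17027 and 16632, and Gm24083 had 14971 and 14692. Gm25252 had 7263 and 6272, Mir299b had 4732 and 4852, and Mir497b had 3941 and 3113. Mir142b had 3459 and 2995, and Gm25750 had 2648 and 1896.

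Libraries that do not keep strand are argued against, since the median share of opposite-strand reads was 0% over 156 genes with at least 1000 own-strand reads. The other explanation tested was that these are reads of a miRNA gene on the other strand that has no line in the files. All 9 genes overlap such a gene in GENCODE M21, against 23 of 1885 other genes (two-sided Fisher's exact test, p = 3.31e-17). The overlapped genes are Mir378a, Mirlet7e, Mir409, Mir191, Mir376a, Mir299a, Mir497, Mir142 and Mir380, in the order above. These opposite-strand reads may therefore belong to those miRNAs, and no biological explanation was tested.

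Reads matching several loci made up 27.1% of reads in replicate 1 and 26.6% in replicate 2, and the files do not say which genes they match. Low counts of miRNA genes with copies may come from reads being set apart in this way. Among 17 miRNA families with both kinds of gene, members that share sequence had the lower median in 13 (exact two-sided sign test, p = 0.0490). Another 2 families with equal medians were left out. Among the 13 was Mir466, with medians of 0 and 0.0673 CPM, below what a count of 0 allows. That p thus rests in part on a family at the floor. The direction held under all 6 definitions of the comparison tried, with the members that share sequence lower in 12 of 19 to 12 of 14 families, but only 2 gave p under 0.05, and p ran from 0.0129 to 0.359. Scarcity of these miRNAs in the tissue cannot be told apart from it, because the reads matching several loci, a mean of 26.8% of reads, are given as a total only. No biological explanation was tested.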

How the results depend on the processing

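The alternative without genes that share sequence was chosen after the data were seen, and the others before. In all, 561 alternative values were computed for 126 results. A change of direction was looked for only in called list shifts and in log2 ratios of the genes named by ratio. It was found 0 times, but those values had been picked as extreme, so this count is no test of stability. No paired analysis was possible because the design has 1 group. With 2 libraries, leaving out either one moves a mean by less than 1 SD whatever the data, so those values are no test of stability. The number of detected genes ran from 274 (at least 10 CPM) to 474 (at least 3 counts), and the number of genes holding 50% of counts from 7 to 10.

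Pearson's r was 0.974 with a pseudocount of 0.1 CPM, 0.996 with 10 CPM and 0.991 for genes with a mean count of at least 10. The number of differing genes was 35 with no count filter, 9 at a mean count of at least 100, 60 at 1.5-fold and 211 with no fold threshold, which follows from the number of genes let in.

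With Mir10a left out of the total, other shares rose by construction: let-7 to 16.1%, miR-99/100 and miR-125 to 7.62%, miR-17-92 to 7.34%, endothelium to 5.81%, stroma to 4.02%, miR-200 to 2.73%, miR-181 to 1.11%, Sfmbt2 families to 0.622%, neural to 0.0850%, leukocyte to 0.0779%, and miR-34 and miR-449 to 0.0777%. The Hox list, which lost Mir10a itself, dropped to 10.6%. With both strands counted, miR-17-92 stood at 6.07%, miR-99/100 and miR-125 at 6.30%, and leukocyte at 0.112%, the last through reads opposite to Mir142b. Without genes that share sequence, miR-99/100 and miR-125 stood at 6.85%, miR-17-92 at 6.30%, endothelium at 5.28%, Dlk1-Dio3 at 2.03%, miR-181 at 0.750%, miR-34 and miR-449 at 0.0707%, pluripotency at 0.00253% and Sfmbt2 families at 7.2e-06%.

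Of the list shifts, Dlk1-Dio3 and miR-200 stayed outside the central 95% of random lists under every alternative run. The TMM and DESeq2 scalings move all genes alike, so they could not move a list against random lists. The miR-200 members share no sequence and all passed the count filters. For them, these alternatives changed the random lists only. The muscle list was inside the central 95% without genes that share sequence, at -0.22 and the percentile 6.88. The kidney-enriched list was outside it at -0.49 for a mean count of at least 100 and at -0.48 without genes that share sequence. With no count filter, the endocrine list at 1.14 and the pluripotency list at 0.89 were outside it too. The cause was not tested. Depth limits genes near 1 CPM, where 3 counts are 0.404 and 0.512 CPM.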

Other observations

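The tests of an origin or explanation in this part, and the cluster ranges without members that share sequence, were chosen after the result was seen, while the list medians and their percentiles had been fixed before. Neighbouring miRNA genes of some clusters differed widely in count, while in others they were close, such as Mir181c and Mir181d at 1.35 times in mean CPM. In the chromosome 14 cluster, the most abundant member, Mir17, exceeded the least abundant, Mir19b-1, by 1791 times in mean CPM, and in the X chromosome cluster Mir322 exceeded Mir450-2 by 4164 times. Mir19b-1 and Mir450-2 share sequence with other miRNA genes, so reads that match several loci are missing from their counts. Among the members that share none, the ranges were 597 times (Mir17 over Mir19a) and 223 times (Mir322 over Mir450b). The miR-181 pair in introns of Nanos3 moved apart between the pools. Mir181c had a log2 ratio of -0.36 and its neighbour Mir181d one of 0.41. Mir351 had a log2 ratio of 0.68 while Mir322 in the same cluster stood at -0.07.

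Of 40 Dlk1-Dio3 genes with enough counts, 36 were higher and 4 lower in replicate 2, and 32 lay above the median of all genes. The 6 members of the list that were not analysed are not among the 40. Mir127 had a log2 ratio of 0.56, Mir411 of 0.53 and Mir487b of 0.03. Mir541, chosen after its value was seen, stood at 1.08. Hairpin GC content, which followed the log2 ratio weakly (Spearman's rho 0.12 over 378 genes), is argued against as the whole cause. After a line on it was taken out, the list's median residual was 0.23 over 40 members, above 99.99% of random lists. The list's excess over the median of all genes was 0.30, against 0.21 before. This covers the whole hairpin only, and GC content of the sequenced RNA of under 30 nt was not tested. A change in library totals is argued against as the whole cause, since it moves all genes alike, while the list's median exceeded that of all genes by 0.21 and lay above 99.75% of random lists of matched expression. These are the values that mark the pattern, and no separate test of it. More neural tissue in replicate 2 may be a source and stays open, since the members of the neural list went both ways, with 5 of 8 higher and a median of 0.12 at the percentile 38.6. Mir122 (0.98) and the erythroid (0.54) and endocrine (0.62) medians were higher in replicate 2 as well, while the muscle median was lower (-0.38). Other tissue as a source was not tested through them. No biological explanation can be set against these, since the pools belong to 1 group.

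Mir6236, which had the largest ratio between the pools among genes with a mean count of at least 100, was searched for sequence shared with other annotated transcripts. At most 2.88% of its 20-nt stretches, 3 of 104, were found in any of them (Wdfy2), so the search gave no other origin for its reads. It covered GENCODE M21 transcripts other than miRNAs, in their own direction only. An origin in sequence outside that set was not searched for and stays open. The other genes named by ratio were searched too. All 75 stretches of Mir770 lie within Meg3, its host, and all 80 of Mir138-1 within Gm47135, its host. Mir138-1 also shared 5 stretches (6.25%) with C78859, and Mir206 shared 41 of 54 with Gm28653, its host.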
